A study of Homo sapiens with 4 samples.

How the data were processed

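Total RNA from A549 and H1299 cells, grown with 10% fetal bovine serum and transfected with scramble or hMOF siRNA, was turned into biotinylated cRNA from 6 ug per sample, per the labels, and measured on Affymetrix arrays with 54675 probe sets. Each of the 4 combinations of line and siRNA has 1 array. The deposited values are linear signal intensities per probe set, made by the authors with MAS5 per the labels. Its version, scaling target and background settings are not given in the sources used here. No value lay below 1, and 4 to 9 values per array stood at that minimum. The arrays had median signals between 73.3 and 75.3. MAS5 estimates vary most at low signal, which widens ratios of dim genes. Detection calls and scanner files were not used here, and the siRNA sequences, the time after transfection and the number of cultures are not given in the labels used here.

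Groups were taken from the source name of each array, and the abbreviations in the titles follow the same split. The treatment tag names the other siRNA on 2 of the 4 arrays, and that tag was not used. Arrays of the same cell line were treated as a pair. Pearson correlations of their log2 signals were 0.988 and 0.983, against 0.889 to 0.9001 between lines.

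Genes were named through the platform's probe annotation. Of the probe sets, 41097 had 1 gene, 1801 had several and 11721 that were not controls had none, and 62 were controls. The symbols were looked up by gene identifier in a RefSeq gene table of the GRCh38.p14 assembly, which changed the symbol of 0 probe sets. It lacked the identifier of 54 probe sets, and those kept the annotation's name. Probe sets with several genes or none entered no gene-level result, and 59 probe sets of XIST and Y-linked genes were left out. No coordinates were used. Genes on the fixed lists that the annotation did not name with a single gene, or that fell below the filter, are not analysed here, among them all 11 members of 1 of the 30 lists.

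Settings were fixed before the data were examined. The offset added to every signal before log2 was 29.06, the 20th percentile of all signals. It shrinks ratios of dim genes, so fold changes are those of signal plus offset. Probe sets were kept when their mean signal over the 4 arrays was at or above 78.1, the 50th percentile of such means. Each gene was represented by its kept probe set with the highest mean signal, which left 12819 of 19740 genes. No further normalization was applied. All ratios are hMOF siRNA over scramble within a line, unless H1299 over A549 is named.

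Within a line, genes were counted at a fixed 2-fold size without a test. Over both lines, limma 3.58.1 in R 4.3.3 (lmFit and eBayes) was fitted to the 4 arrays with terms for cell line and siRNA, and Benjamini-Hochberg adjusted p values were held to a threshold of 0.05. The fit has 1 residual degree of freedom per gene, to which eBayes added 3.72 prior degrees of freedom. The siRNA test takes the lines as repeats, and the test between lines takes the siRNAs as repeats. These p values measure only the spread between these arrays. Nothing in the labels says whether cultures were repeated. Gene lists were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over 29 lists. Per line, a list's median was placed among 10000 random lists of the same size matched on mean signal in 20 bins, as a description of those arrays. Lists needed at least 3 measured genes. Figures were drawn with matplotlib 3.10.9.

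The rule for named genes, fixed before the data were examined, took KAT8, the 12 higher and 12 lower genes with the largest smaller ratio of the 2 lines among those 2-fold in both, the 5 highest and 5 lowest ratios per line, and the 10 largest differences each way between lines past the threshold. It also took members of the fixed lists as examples and genes 2-fold in opposite directions, of which there were 0.

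The procedure was tested in 20 runs on simulated data for the siRNA effect over both lines, with 12819 genes drawn independently. Of these genes, 200 were changed 2-fold or 4-fold, and the 19 measured hypoxia and glycolysis genes were shifted by log2 0.5. The procedure recovered 70.3% of genes changed 2-fold and 98.4% of those changed 4-fold, and 6.66% of its calls were false. Unchanged genes came out 2-fold in both lines with the same sign 6.85 times per run and with opposite signs 6.45 times. The real arrays gave 0 genes with opposite signs, so the simulated noise did not match theirs and these rates may not carry over.

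The alternatives were an offset of 0 or of the 40th percentile (56.5), no filter or one at the 70th percentile (179), quantile normalization, centring each array on its median, averaging a gene's kept probe sets, leaving out _x_at probe sets, dropping the block, eBayes with trend, an estimated correlation in camera, and leaving out each line or siRNA in turn. A loess of each line's ratio on signal was added after the data were seen.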

Results

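Gene expression was measured in 2 human non-small cell lung cancer lines after siRNA transfection against hMOF, the histone acetyltransferase encoded by KAT8 that acetylates histone H4. A549 is an adenocarcinoma line with features of alveolar epithelium, and H1299 is a line derived from a lymph node metastasis. Each line was transfected with a scramble control siRNA or with hMOF siRNA, and 1 array was made per line and siRNA, 4 arrays in all. No group was replicated, so a ratio within a line carries no error of its own and the lines were the only repeats of the siRNA comparison. The median signal was 75.2 and 75.3 on the A549 scramble and hMOF siRNA arrays, and 73.3 and 73.7 on the H1299 arrays. Across the 12819 genes analysed, the median log2 ratio of hMOF siRNA to scramble was −0.02 in A549 and −0.01 in H1299. Across all non-control probe sets, unfiltered, log2 values correlated at r = 0.988 between the A549 arrays and at r = 0.983 between the H1299 arrays. Between arrays of different lines they correlated at 0.889 to 0.9001. The 3'/5' signal ratio of the GAPDH control probe sets, a measure of RNA integrity, was 1.18 and 1.20 in A549 and 1.10 and 1.09 in H1299 (scramble and hMOF siRNA). That of the ACTB control probe sets was higher, at 3.11 and 2.78 in A549 and 2.89 and 2.64 in H1299, and lower with hMOF siRNA than with scramble in both lines. The number of arrays limits the precision of every value.

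The siRNA target was examined first. KAT8 signal (probe set 221820_s_at) was 402 with scramble and 106 with hMOF siRNA in A549, and 241 and 61.8 in H1299. The signal left was 26.4% in A549 and 25.6% in H1299, 26.0% ± 0.54 (SD, n = 2 lines). On the log2(signal + 29.06) scale used for all ratios, KAT8 fell by 1.67 in A549 and by 1.57 in H1299 (mean −1.62 ± 0.07, SD, n = 2 lines; limma adjusted p = 0.0290). The other KAT8 probe set, 214885_at, lay below the signal minimum, at 61.6 and 51.6 in A549 and 61.7 and 39.8 in H1299. The direction followed the source names of the arrays, whereas the treatment tag of 2 arrays contradicts their source name. With no block for cell line, the fall in KAT8 did not pass the test (limma adjusted p = 0.9999), and over the 9 alternatives that kept the block the adjusted p ran from 0.00420 to 0.0321.

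The next comparison asked which genes differed with hMOF siRNA in each line. In A549, 92 genes were at least 2-fold higher and 146 at least 2-fold lower. The highest ratios belonged to the antisense transcript ZBED3-AS1 (signal 85.5 to 832), the histone H2B gene H2BC5 (244 to 1425), the collagen gene COL5A1 (704 to 3236), the secreted matrix protein gene CCDC80 (319 to 1493) and VWC2 (34.8 to 232). The lowest were GPAT3, a glycerol-3-phosphate acyltransferase (467 to 71.3), the kinase gene HIPK3 (3024 to 697), RNF141 (1204 to 287), LOC728392 as the annotation names probe set 218380_at (811 to 197) and STRADB, a pseudokinase (1161 to 311). In H1299, 156 genes were at least 2-fold higher and 284 at least 2-fold lower. The highest ratios there belonged to the pseudogene ANKRD30BP3 (6.85 to 491), the histone H2A gene H2AC15 (64.2 to 949), PCP4L1 (39.6 to 319), the mitochondrial import receptor gene TOMM22 (258 to 1398) and the neurofilament gene NEFH (264 to 1393). The lowest were TTLL6 (527 to 19.9), the sulfate transporter gene SLC13A1 (347 to 6.68), LDAF1 (978 to 82.1), LOC101928697 (285 to 13.3) and HIPK3 (2702 to 407). The smaller H1299 signals of ANKRD30BP3, TTLL6, SLC13A1 and LOC101928697 lay under the offset, so their ratios and ranks are set in part by it. SLC13A1 was at −5.70 and TTLL6 at −4.73 with no offset, against −3.39 and −3.51 with it, which turns their order. In the other line ANKRD30BP3 stood at 10.1 and 9.47, SLC13A1 at 2.79 and 5.88, both under the offset, and ZBED3-AS1 at 96.5 and 97.7. These counts rest on a rule of size with no test, since each is 1 array against 1 array. The A549 count of higher genes was 139 with no offset added before taking logs.

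Many of the same genes responded in both lines. Of the 12819 genes, 37 were at least 2-fold higher in both lines and 100 at least 2-fold lower in both, and none were 2-fold in opposite directions. Independent lists of these sizes would share 1.12 and 3.23 genes. All 137 passed limma's test over both lines, with cell line as a block. That test averages the same 2 ratios by which the genes were chosen, so it is no independent support. Averaging a gene's probe sets gave 23 higher and 71 lower genes, and 87 of the 137 were among them. Ranked by the smaller of the lines' ratios, the falls shared by the lines began with HIPK3 (log2 −2.07 in A549, −2.65 in H1299), RNF141, a RING finger protein gene (−1.96, −2.41), STRADB (−1.81, −2.30) and SKP2 (−1.76, −2.07). SKP2 encodes the F-box subunit of a ubiquitin ligase that directs CDK inhibitors to degradation, and its signal was 1163 and 324 in A549 and 1385 and 308 in H1299 (mean log2 −1.91, SE 0.13; limma adjusted p = 0.0290). Only 1 SKP2 probe set passed the signal minimum, 203625_x_at, whose suffix marks probes that can match other transcripts. Of the probe sets below it, 210567_s_at gave −1.42 and −0.95 and 203626_s_at −0.10 and −0.30. Probe set 211042_x_at, which has no single gene in the annotation, had signals close to those of 203625_x_at. They were 1237 and 353 in A549 and 1547 and 365 in H1299 (scramble and hMOF siRNA). Whether both probe sets read the same transcript was not tested.

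Other genes that fell in both lines were GPAT3 (−2.30, −1.70), SAMTOR, which encodes a methionine-pathway sensor for mTORC1 (−1.69, −2.15), SMIM15 (−1.68, −1.91), the integrin subunit gene ITGA2 (−1.67, −2.34), the ubiquitin-conjugating enzyme gene UBE2Q1 (−1.66, −2.06), the protein kinase A regulatory subunit gene PRKAR2B (−1.64, −2.12), ASPH, an aspartyl hydroxylase (−1.64, −2.19), and SMAD5, a mediator of BMP signalling (−1.63, −1.97). The genes that rose in both lines, ranked by the smaller ratio, began with GANAB, the catalytic subunit of an endoplasmic reticulum glucosidase (1.68, 1.85), FMC1, a mitochondrial ATP synthase assembly factor (1.57, 2.19), the Mediator subunit gene MED11 (1.56, 1.88), H2BC5 (2.41, 1.52), RABL6 (1.65, 1.48) and TOMM22 (1.44, 2.31). They were followed by the kinesin gene KIF1C (1.42, 1.62), the stress granule protein gene G3BP2 (1.41, 1.44), the nucleolar phosphoprotein gene NOLC1 (1.41, 1.70), TUFT1 (1.39, 1.62), ZCCHC3 (1.34, 1.69) and EMC6, a subunit of a membrane protein insertase (1.33, 1.90). Adjusted p values from limma for these 24 genes lay between 0.0290 and 0.0348. Each gene stayed past the threshold under the other offsets, filters, scalings and probe set rules that kept a probe set for it. When all kept probe sets of a gene were averaged, the mean log2 change was smaller by over 1.5 times for HIPK3 (−1.13), RNF141 (−1.33), ASPH (−0.72), UBE2Q1 (−1.05), RABL6 (0.66) and G3BP2 (0.81).

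**Figure D1:**
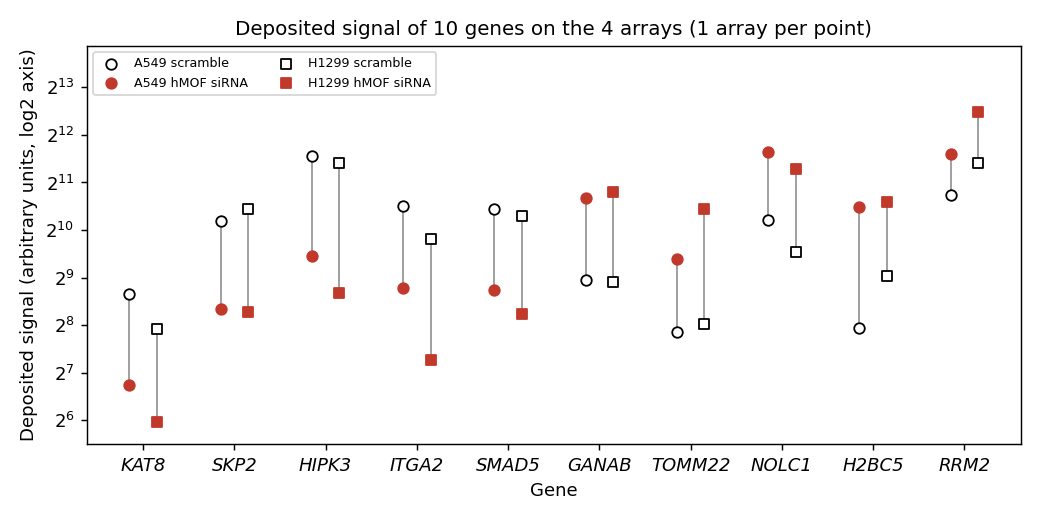
Deposited signal (arbitrary units, log2 axis) of 10 genes on the 4 arrays; circles are A549, squares H1299, open symbols scramble and filled symbols hMOF siRNA, 1 array per point. KAT8, SKP2, HIPK3, ITGA2 and SMAD5 were lower and GANAB, TOMM22, NOLC1, H2BC5 and RRM2 higher with hMOF siRNA in both lines.

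Over both lines limma called 147 genes higher and 308 lower with hMOF siRNA, 3.55% of the genes tested, and 3051 genes had an unadjusted p under 0.05. The counts depended on the scaling, with 275 higher and 357 lower after quantile normalization and 591 and 614 after centring each array on its median. The lower share of calls was 67.7%, 56.5% and 51.0% under these 3 scalings, and its drop came with more higher calls, not with fewer lower calls. Among genes 2-fold in both lines, 37 higher and 100 lower, the counts were 49 and 85 after quantile normalization and 49 and 83 after centring. Genes selected in A549 alone mostly pointed the same way in H1299, 138 of the 146 lower genes (94.5%) and 79 of the 92 higher genes (85.9%). The reverse held for 261 of the 284 genes lower in H1299 (91.9%) and 149 of the 156 higher (95.5%). The log2 ratios of the lines correlated at Pearson r = 0.626 and Spearman rho = 0.560 across the 12819 genes, which are not independent replicates. The test had 1 residual degree of freedom per gene and 2 lines as repeats, and its lowest adjusted p, 0.0290, was shared by 82 genes. Without the block for cell line it called 0 genes higher and 0 lower, with 350 at an unadjusted p under 0.05.

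**Figure D2:**
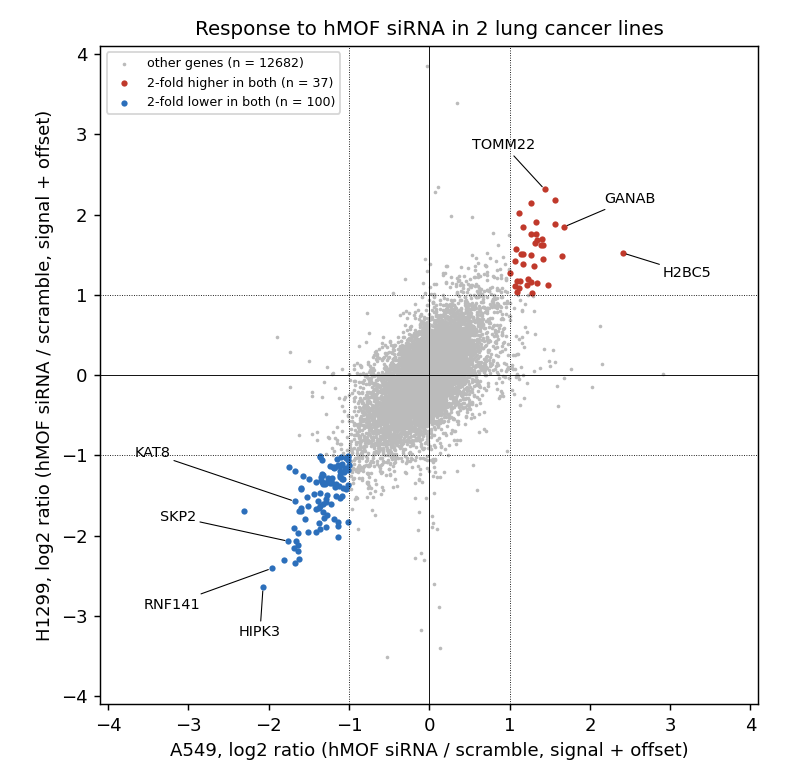
Log2 ratio of hMOF siRNA to scramble (signal + offset) per gene in A549 (x axis) and H1299 (y axis), 12819 genes, 1 array pair per line. Red points are the 37 genes at least 2-fold higher and blue points the 100 at least 2-fold lower in both lines, and dotted lines mark 2-fold.

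Of 30 gene lists fixed before the data were examined, 29 could be tested and 4 moved with hMOF siRNA over both lines by limma's camera test with its preset inter-gene correlation. Core and variant histone genes rose as a list, with a median log2 ratio of 0.84 in A549 and 0.41 in H1299 (camera adjusted p = 0.00112, and 0.982 with an estimated correlation). Of 10 histone genes measured, 4 rose, none fell and 6 did not pass the test. Adjusted over the list alone, 5 rose. Those called were H2BC5, H2BC4 (signal 24.5 to 120 in A549, 186 to 438 in H1299; log2 1.48 and 1.12), H2AJ (1.12, 1.17) and H4C8 (1.004, 0.69; limma adjusted p = 0.0474). H2AC6 was at 1.32 and 0.51, and the linker histone gene H1-2 at −0.02 and −0.04, and neither passed. H2BC5 and H2AJ were measured on _x_at probe sets. Without such probe sets H2AJ was at −0.03 and H2BC5 had no kept probe set. The A549 scramble signal of H2BC4 lay under the offset, so its A549 ratio is set in part by the offset. The call on H4C8 was lost with no signal filter. The list's mean over both lines was 0.68, and 0.40 without _x_at probe sets. Over the 8 alternatives with the preset correlation this mean ran from 0.40 to 0.77 and the adjusted p from 0.000927 to 0.0454.

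The hypoxia and glycolysis list was lower, although none of its 19 measured genes passed alone, in either adjustment. Its median log2 ratio was −0.43 in A549, with 19 of 19 genes below 0, and −0.09 in H1299, with 14 of 19 (camera adjusted p = 0.00608, and 0.982 with an estimated correlation). The largest values belonged to NDRG1, a stress-responsive gene (−1.46 in A549, −0.74 in H1299), and ENO2, a neuronal enolase (−1.05, −0.28). The interferon response list was lower as well, at −0.39 in A549 and −0.10 in H1299 (camera adjusted p = 0.0129, and 0.982 with an estimated correlation). None of its 20 genes passed over all genes and 4 fell when adjusted over the list alone. IRF7, the transcription factor of interferon induction, was at −1.40 and −0.71, and IFIT3 at −0.94 and −0.62. In A549 the medians of both lists lay below all 10000 random lists of matched size and signal, at percentile 0.00, and in H1299 they lay at percentiles 15.9 and 7.56. The adjusted p with the preset correlation ran from 0.000293 to 0.0210 for hypoxia and glycolysis and from 0.00253 to 0.0210 for the interferon list.

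Cholesterol synthesis genes were lower, with a median of −0.50 in A549 and −0.19 in H1299 (camera adjusted p = 0.0241, and 0.982 with an estimated correlation). Of 14 measured, 2 fell, none rose and 12 did not pass; 5 fell when adjusted over the list alone. The called genes were DHCR7, which reduces the last sterol intermediate to cholesterol (−1.75, −1.14), and HSD17B7, a sterol ketoreductase (−0.76, −0.82). HMGCS1, an early enzyme of the pathway, was at −0.92 and −0.12 and did not pass. The call on this list was lost when _x_at probe sets were left out (camera adjusted p = 0.278) and when probe sets were averaged (0.0653), and its adjusted p over the preset-correlation alternatives ran from 0.00251 to 0.278. None of the 29 lists passed with an estimated correlation. In simulated data of this design, a list shifted by 0.5 was called in 20 of 20 runs with the preset correlation. With an estimated one it was called in 0 of 20, so that version could not detect such a shift here. Simulated genes were drawn independently of each other, so these runs cannot show whether preset calls hold in correlated lists. The estimated correlations were 0.07 for histone genes and 0.44 for hypoxia and glycolysis, against the preset 0.01. They were 0.12 for interferon response and 0.71 for cholesterol synthesis. With 1 residual degree of freedom, each estimate depends only on how a list's genes split between a larger ratio in H1299 and in A549. It does not measure how genes vary together. The correlation within these lists is thus not known, and the 4 preset calls remain uncertain.

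**Figure D3:**
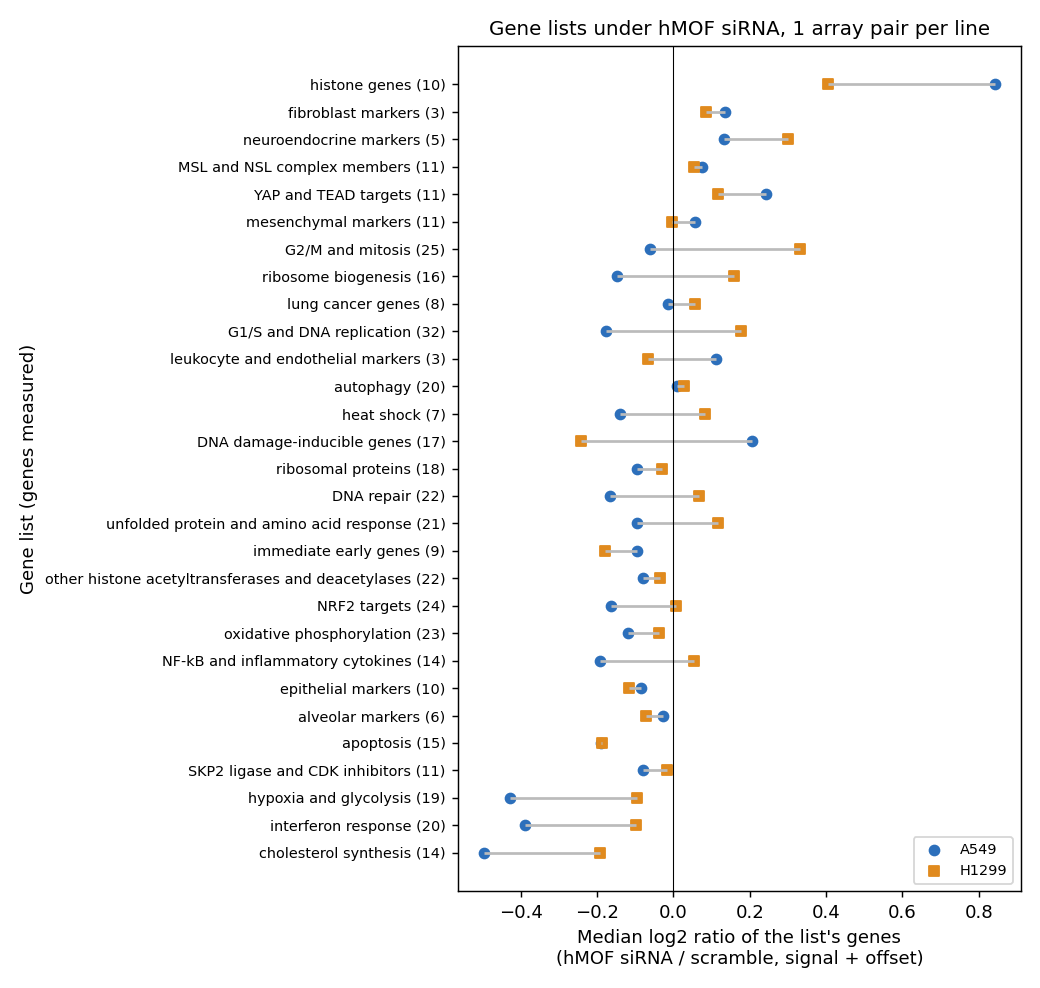
Median log2 ratio of hMOF siRNA to scramble for 29 gene lists, blue circles A549 and orange squares H1299, with the number of genes measured in brackets and lists ordered by their mean over both lines. Histone genes sit at 0.84 and 0.41, cholesterol synthesis at −0.50 and −0.19.

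The lists closest to the targeted complex did not move as lists. Among 11 members of the MSL and NSL complexes, in which hMOF acts, MSL1 was called higher (1.10 in A549, 0.99 in H1299), none fell and 10 did not pass (camera adjusted p = 0.444). The mean MSL1 change was 0.31 when its probe sets were averaged, and then did not pass the test. Of 22 other acetyltransferases and deacetylases, KAT6A, a MYST family relative of hMOF, fell (−0.84, −1.01) and 21 did not pass (camera adjusted p = 0.701). In the list of the SKP2 ligase and CDK inhibitors, SKP2 fell and the other 10 genes did not pass (camera adjusted p = 0.495). Adjusted over the list alone, 1, 1 and 2 genes of these 3 lists were called. The CDK inhibitor genes measured in this list were at −0.01 and −1.19 for CDKN1A, −0.08 and −0.18 for CDKN1B, −0.45 and −0.89 for CDKN1C, and −0.11 and −0.88 for CDKN2D.

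Cell cycle and DNA damage-inducible genes had medians on opposite sides of 0 in the lines. The G1/S and DNA replication list, 32 genes, stood at −0.18 in A549 (percentile 1.29 of random lists) and 0.18 in H1299 (percentile 99.7). The G2/M and mitosis list, 25 genes, stood at −0.06 and 0.33 (percentiles 41.7 and 100). DNA damage-inducible genes, 17 measured, stood at 0.21 in A549 (percentile 99.8, 12 above 0) and −0.24 in H1299 (percentile 2.34, 12 below 0). Their list was fixed as p53 targets. Over both lines none of the 3 lists passed (camera adjusted p = 0.701, 0.369 and 0.894), and their mean log2 changes were 0.02, 0.10 and −0.04. For the DNA damage-inducible list the test statistic pointed up while the mean was below 0, and for the G1/S list the median over both lines was −0.01 with a mean above 0. Their called members were RRM2, the ribonucleotide reductase subunit of S phase, which rose (0.86, 1.07), the cyclin gene CCNB2, which fell (−0.98, −1.19), and the repair gene XPC, which rose (0.95, 0.90). Each list had 1 called member over all genes and 1 when adjusted over the list alone. DDB2 was at 0.91 in A549 and −0.09 in H1299, MDM2 at −0.22 and −0.63, below 0 in both, and the centromere protein gene CENPF at −0.05 and 1.44. These lists were not alone. Medians of DNA repair (−0.17 in A549, 0.07 in H1299) and ribosome biogenesis (−0.15, 0.16) also lay on opposite sides of 0. Their H1299 minus A549 medians lay at percentiles 99.99 and 99.91 of random lists. For hypoxia and glycolysis, interferon response and cholesterol synthesis, called lower over both lines, these percentiles were 99.71, 99.95 and 99.99. With 1 array pair per line the difference between lines was not tested.

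The last comparison set H1299 against A549, with siRNA as a block. Of the 12819 genes, 3221 were higher in H1299 and 3486 higher in A549 by limma, 52.3% in all. The genes named here are those with the largest differences on the log2(signal + offset) scale. AKR1C3, an aldo-keto reductase gene, had signals of 15314 and 14098 in A549 against 10.4 and 10.7 in H1299 (log2 H1299 over A549 −8.54; limma adjusted p = 4.45e-05). ALDH1A1 (−8.24), AKR1B10 (−7.92), the kynureninase gene KYNU (−7.70), AKR1C2 (−7.62), the surface glycoprotein gene CD24 (−7.38), S100A6 (−7.22), the carbonic anhydrase gene CA12 (−7.08), AKR1C1 (−7.06) and UBE2E1 (−6.90) were also higher in A549. Without _x_at probe sets the AKR1C2 value was −2.47, and averaging probe sets gave −4.65 for CA12. CTAG2, a cancer-testis antigen gene, had signals of 3728 and 3724 in H1299 against 23.3 and 21.5 in A549 (log2 6.19; limma adjusted p = 4.45e-05). MAGEA4 (6.19), GTSF1 (5.87), TDRD12 (5.74), BEX1 (5.68), MAGEA12 (5.68), the homeobox gene HOXB2 (5.66), PLAC8 (5.36), MAGEA1 (5.27) and TDRD9 (5.13) were also higher in H1299. In the line with less signal, 19 of these 20 genes lay under the signal minimum on both arrays and 10 under the offset, so their log2 values and order are set in part by the offset and not measured to these decimals. With no offset and with the offset at the 40th percentile, AKR1C3 was at −10.45 and −7.78 and CTAG2 at 7.38 and 5.58. AKR1C and MAGEA genes are families of near-identical copies, so probes of these members can bind transcripts of their relatives.

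By camera with the preset correlation, 8 of 29 lists differed between the lines, and 0 with an estimated correlation (adjusted p = 0.862 for these 8 with an estimated correlation). The estimated version rests on 1 residual degree of freedom, so its outcome speaks neither for nor against these calls. NRF2 targets, genes of the antioxidant response, were higher in A549 (mean log2 H1299 over A549 −3.18; 20 of 24 called higher in A549, 1 in H1299 and 3 not; camera adjusted p = 1.17e-08), including NQO1 (−1.61) and GPX2 (signal 4278 and 2348 in A549, 25.6 and 26.2 in H1299). Epithelial markers were higher in A549 (−2.78; 7 of 10 called higher in A549, 1 in H1299 and 2 not; adjusted p = 0.00286), including the keratin gene KRT7 (−5.48) and the cadherin gene CDH1 (signal 1535 and 1562 in A549, 8.04 and 7.61 in H1299). NF-kB and inflammatory genes were higher in A549 (−2.10; 11 of 14 called there and 2 in H1299; adjusted p = 0.00451), including CXCL8 (signal 5250 and 3037 in A549, 9.72 and 6.95 in H1299) and PTGS2 (1870 and 1874, 7.18 and 11.7). DNA damage-inducible genes (−0.84; 8 of 17 higher in A549, 1 in H1299) and interferon response genes (−0.76; 12 of 20 higher in A549, 4 in H1299) passed at camera adjusted p = 0.0434. In H1299, G2/M and mitosis genes were higher (0.61; 16 of 25 called, 1 higher in A549; adjusted p = 0.00286), including NDC80 (2.44). The G1/S and DNA replication list was higher too (0.37; 17 of 32 called, 4 higher in A549; adjusted p = 0.0434), including CDT1 (1.73). Lung cancer genes were higher in H1299 (1.53; 4 of 8 called, 1 higher in A549; adjusted p = 0.0434). The list's median was 0.51, and its mean was carried by CDKN2A, CDKN2B and MTAP, neighbouring genes with a mean of 4.13, while the other 5 genes averaged −0.03. These 3 genes had signals of 8.31 to 46.5 in A549 and 576 to 1317 in H1299. In these 8 lists, genes with signals under the offset in 1 line, such as GPX2, CDH1, CXCL8, PTGS2, CDKN2B and MTAP, enter the list means with values set in part by the offset. Adjusted over the list alone, the counts differed by at most 2 genes. The calls at 0.0434 were lost under at least 1 other setting each, with adjusted p up to 0.243.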

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

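The tests of an off-target siRNA action, of cross-hybridising histone probe sets and of cells in S phase, and the loess per line, were chosen only after the results were seen. The differences between lines given here were not tested, since each line has 1 array per siRNA.

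The G1/S and DNA replication list and the DNA damage-inducible list stood on opposite sides of 0 in the lines: the median of H1299 minus A549 log2 ratios was 0.42 for G1/S genes, positive in 30 of 32, and −0.50 for DNA damage-inducible genes, negative in 16 of 17. G2/M and mitosis genes differed by 0.43, positive in 24 of 25. Scaling of the arrays as the whole cause is argued against, because at least 87.1% of each median difference was left after quantile normalization or a loess per line. A few extreme members are argued against too, because leaving out the 5 largest members of a list left at least 71.0% of its median difference. A difference between the lines in their response may be biological, as a hypothesis, and stays untested, since a difference in culture or harvest between single arrays cannot be separated from it. Nor was the difference particular to these lists. The median of H1299 minus A549 log2 ratios was 0.32 for cholesterol synthesis, 0.30 for DNA repair and 0.29 for ribosome biogenesis. It was 0.27 for interferon response and 0.25 for hypoxia and glycolysis.

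Probe set 218380_at, which the annotation names LOC728392 and whose present gene was not settled here, stood on opposite sides of 0 in the lines, at −1.89 in A549 (signal 811 to 197) and 0.47 in H1299 (744 to 1045), a difference of 2.37.

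Among 4462 probe sets above the signal minimum that have no gene or several genes in the annotation, 20 were at least 2-fold the same way in both lines, 9 higher and 11 lower, and 0 were 2-fold in opposite directions. By the smaller of the lines' values, the largest were 226781_at (1.58 in A549, 2.38 in H1299) and 207181_s_at (1.51, 1.38) among the higher, and 211042_x_at (−1.73, −1.999) and 224818_at (−1.70, −1.54) among the lower.

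Genes moved together in the lines, with 137 at least 2-fold the same way in both and 0 in opposite directions. Array noise that is independent between the lines is argued against, because at 1.5-fold 623 genes shared a sign and 6 did not, 0.963%. A technical difference shared by both hMOF siRNA arrays could also give shared signs and was not tested. The ACTB 3'/5' ratio was lower with hMOF siRNA in both lines (3.11 to 2.78 in A549, 2.89 to 2.64 in H1299). That of GAPDH went from 1.18 to 1.20 in A549 and from 1.10 to 1.09 in H1299. Single faulty probe sets as the whole cause are argued against, because in the 76 genes with another kept probe set its median log2 ratio, in the gene's direction, was 0.91 in A549 and 0.813 in H1299, and 64 went the gene's way in both lines. Scaling tied to intensity stays open as a partial cause, since 122 of the 137 genes were still 2-fold in both lines after quantile normalization and 122 after the loess, just under the bound set for excluding it. An off-target action of an siRNA could account for shared changes, among them the 100 lower genes, and cannot be told apart from loss of hMOF, since each siRNA name is the same in both lines and sequences were not used here.

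Histone genes as a list were higher in both lines. Cross-hybridising probe sets could account for part of it and stay open, since the 4 members measured by plain _at probe sets had a mean log2 ratio of 0.79 in A549 and 0.404 in H1299, but 0.56 and 0.16 without H2BC4, whose A549 scramble signal lay under the offset. A larger share of cells in S phase stays open in both lines, since it was not measured and transcripts do not count cells. In A549 the median of G1/S genes was −0.175, at percentile 1.29 of random lists, while histone genes had a median of 0.84. There 25 G1/S genes lay below 0 and 7 above, which argues against a general rise of G1/S transcripts in A549. RRM2, the called member of that list, rose all the same (0.86 in A549). In H1299 the G1/S median was 0.18. An effect of hMOF loss on histone transcripts stays open too, untested beside an off-target action of the siRNA.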

How the results depend on the processing

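The loess per line was chosen after the data were seen, and all other alternatives before. With the cell line block dropped (no pairing of arrays by line), limma called 0 genes higher and 0 lower with hMOF siRNA, with 350 at an unadjusted p under 0.05, and KAT8 kept −1.62 at an adjusted p of 0.9999; the fit then counts the difference between lines as spread. With the siRNA block dropped, 2012 genes were higher in H1299 and 2274 in A549. With an offset of 0, 139 genes were 2-fold higher in A549, 2 were higher in A549 and lower in H1299, and KAT8 was at −1.92 in A549 and −1.97 in H1299, against −1.50 and −1.33 with the offset at the 40th percentile. Averaging probe sets gave 23 genes 2-fold higher in both lines. Quantile normalization gave 275 genes higher, and median centring 591 higher and 614 lower, with KAT8 at −1.59 in A549. Median centring used the median of all non-control probe sets above the signal minimum, with or without a single gene. It shifted every ratio of a line by the same amount and left the median of the analysed genes at 0.06 in A549 and 0.04 in H1299. Why the call counts changed with the scaling was not tested. H2AJ turned to −0.0329 without _x_at probe sets, where SKP2, H2BC5, CTAG2, MAGEA12 and MAGEA1 had no value and so were not checked.

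Estimating the correlation in camera ended every list call. That version rests on 1 residual degree of freedom, so the loss speaks neither for nor against the calls. Each list's mean stayed as it was. These means were −0.34 for interferon response, −0.37 for cholesterol synthesis, −0.33 for hypoxia and glycolysis and 0.68 for histone genes with hMOF siRNA. For H1299 over A549 they were 0.37 for G1/S, 0.61 for G2/M, −0.84 for DNA damage-inducible genes, −3.18 for NRF2 targets, −0.76 for interferon response, −2.10 for NF-kB, −2.78 for epithelial markers and 1.53 for lung cancer genes. Cholesterol synthesis missed the threshold at −0.31 with probe sets averaged and −0.30 without _x_at probe sets. Between lines, G1/S (0.37), interferon response (−0.72) and lung cancer genes (1.53) missed it with the filter at the 70th percentile, and so did G1/S (0.35), interferon response (−0.71) and lung cancer genes (1.18) with probe sets averaged, and DNA damage-inducible genes (−0.75) without _x_at probe sets. The unfolded protein list (−0.36) and oxidative phosphorylation (0.24) passed with no filter, and the latter also with the offset at the 40th percentile (0.24).

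For the 24 genes named as shared by the lines, 190 values under the other offsets, filters, scalings and probe set rules kept their direction and side of the threshold and 0 did not. For the 20 genes named between lines 157 did and 0 did not. Both sets were chosen for the largest values on these same arrays, so their stability was in part set by that choice. Of all 137 genes 2-fold in both lines, 87 stayed so with probe sets averaged. Leaving out either line left 1 pair of arrays with no test and turned no called direction. For genes this is no check, since every gene called over both lines had the same sign in each line. For genes named within a line, 12 of 153 values moved by over 1.5-fold: those of ANKRD30BP3, SLC13A1, TTLL6, LOC101928697, PCP4L1 and VWC2 with another offset, and of HIPK3 and RNF141 with probe sets averaged. Signal over background limits dim genes such as SLC13A1, at 6.68 in H1299 with hMOF siRNA.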

Other observations

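No test in this part was chosen only after its result was seen, but COL1A1, ACTA2 and VIM were picked as examples after their values were seen. Several called genes stood alone in lists that did not move as a whole. In the unfolded protein and amino acid response list, EDEM1, which helps clear misfolded glycoproteins (−0.96 in A549, −0.98 in H1299), and PHGDH, the entry enzyme of serine synthesis (−1.11, −1.53), fell and 19 of 21 genes did not pass (limma adjusted p = 0.0324 for both; camera adjusted p = 0.886). That list's mean was −0.06 and its median 0.03. COX7C, a cytochrome c oxidase subunit, fell (−1.12, −0.86) while the other 22 oxidative phosphorylation genes did not pass (camera adjusted p = 0.495). ATG9A, an autophagy membrane protein, fell (−0.77, −1.22) and the other 19 autophagy genes did not pass (camera adjusted p = 0.701). LAMP3, a lysosomal protein of alveolar cells, fell (−0.92, −0.86), from 46.4 to 10.8 in A549 and from 445 to 232 in H1299, and the other 5 alveolar markers did not pass (camera adjusted p = 0.701). LAMP3 lost its call with an offset of 0, where its mean log2 change was −1.52 against −0.89. ATG9A lost its call with no filter, where its mean stayed at −0.99. NOLC1 was the 1 called gene of 16 ribosome biogenesis genes, whose medians were −0.15 in A549 and 0.16 in H1299 (camera adjusted p = 0.689).

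The mesenchymal list had medians of 0.06 in A549 (percentile 85.1 of random lists) and −0.00 in H1299, with 0 of 11 genes called (camera adjusted p = 0.665). Of its genes ACTA2 was at 1.43 and 0.32, COL1A1 at 1.10 in A549 with H1299 signals under the offset, and VIM at 0.27 and −0.02, and none of these passed. Epithelial markers had 0 of 10 genes called (0.495) and YAP and TEAD targets 0 of 11 (0.349; medians 0.24 and 0.12). Adjusted over all genes, no called gene was found among 24 NRF2 targets (0.444), 22 DNA repair genes (0.819; medians −0.17 and 0.07), 15 apoptosis genes (0.444; medians −0.19 and −0.19), 14 NF-kB genes (0.495), 18 ribosomal protein genes (0.701), 9 immediate early genes (0.701), 7 heat shock genes (0.975) or 8 lung cancer genes (0.758). Adjusted over all genes, markers of other cell types were not called either, with 3 leukocyte and endothelial genes (0.819), 3 fibroblast genes (0.689) and 5 neuroendocrine genes (0.444); the values in brackets are camera adjusted p. Adjusted over the list alone, 1 NRF2 target rose and 2 fell, 1 neuroendocrine marker rose and 1 fell, and 1 gene fell in each of the apoptosis, mesenchymal and epithelial lists; the other lists of this paragraph had 0.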
